A study of Homo sapiens with 12 samples.

How the data were processed

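MCF10A is an immortalized, non-tumorigenic line of human mammary epithelial cells that is kept in serum-free medium with a ligand of the EGF receptor. Total RNA of 12 samples of these cells was labelled with biotin and measured on Illumina HumanHT-12 version 3 bead arrays. Per the labels, cells grew with 10 ng/ml of epidermal growth factor (EGF) or with 20 ng/ml of amphiregulin (AREG), a lower-affinity ligand of the same receptor. Arrays were made with the ligand present or 24 h after its withdrawal, which gives 4 groups of 3 numbered replicates. The labels do not say whether replicates were separate cultures. Spread between arrays, and every p-value based on it, may therefore measure technical variation alone.

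A table of probe signals and a table of normalized values were deposited. Per the file headers, the first holds the mean bead signal of each probe as an intensity on a linear scale, not normalized and with no detection p-values. The second table was deposited without a stated unit, and its values have the range and the identical distributions of quantile-normalized log2 signal. Each of its 48803 probes was matched one to one with a probe of the signal table by its ranks on the 12 arrays. After that match, the deposited log2 values differed from log2 quantile-normalized signal by at most 0.016. No background had been subtracted in either table.

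Signals were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3, using an offset of 50, and were quantile-normalized across the 12 arrays and taken to log2. As no detection p-values were given, a probe counted as above background when its signal exceeded the mode of the array's signals by 2.33 SDs of the background distribution, a tail probability of 0.01. The SD came from the values under the mode. Probes above background on all 3 arrays of at least 1 group were kept, which left 18790 probes. A detection p-value had been planned for this filter. The plan set an offset of 16 for signals with detection p-values and of 50 for signals without them. The offset of 16 was run as an alternative, chosen once the files were seen.

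Probes were named from the array's annotation table. It gave 1 gene symbol for 28098 probes, several for 13 and none for 20692, and it covered 18852 symbols. For 28059 of the named probes the Entrez number was found in the RefSeq table, and no symbol was changed by it. Of the probes kept, 14987 had a name and 3803 had none. Unnamed probes were tested apart. The brightest probe by mean signal over all 12 arrays stood for each gene, which left 11345 genes. Probes of near-identical family members (UGT1A enzymes, metallothioneins, AKR1C enzymes, histones, PTTG1 and FABP5) can detect more than 1 transcript, so which member changed is uncertain. For the 2890 genes with further probes past the filter, 84.8%, 86.9%, 82.5%, 89.1% and 81% of the other probes of changed genes had the same sign in the 5 comparisons, in the order given next.

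A linear model with 4 group means was fitted to all 12 arrays with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the 11345 genes and a threshold of 0.05. The 5 comparisons were EGF withdrawal (withdrawn minus present), AREG withdrawal, AREG minus EGF with ligand present, AREG minus EGF after withdrawal, and the difference of the withdrawal responses (AREG response minus EGF response). Standard errors come from this model, with 8 residual degrees of freedom plus 8.8 prior ones.

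Gene lists were tested with camera of limma at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. The lists were S phase and DNA replication, mitosis, ERK pathway transcriptional output, EGF-family ligands with their receptors and feedback, interleukin 1 and NF-kB targets, interferon-stimulated genes, invasion and extracellular proteolysis, cell adhesion and hemidesmosome, mesenchymal markers, basal epithelial markers, luminal mammary markers, squamous differentiation, cholesterol synthesis, fatty acid synthesis, glycolysis and glucose transport, hypoxia response, ribosome biogenesis and MYC targets, ATF4 and amino acid response, FOXO targets and quiescence, p53 targets, lysosome and autophagy, NRF2 targets, and markers of fibroblasts and stroma, of leukocytes and of endothelium. Of their 511 genes, 478 had a named probe and 408 were tested.

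The groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined, and so was the rule for naming genes. Per comparison it takes the 8 highest and 8 lowest changes past the threshold (in the pairwise comparisons, among genes whose 2 groups of arrays do not overlap), up to 4 changed members of each list with the largest change, or 1 member where none changed. It adds EGF, AREG, EREG, HBEGF, TGFA, EGFR, ERBB2, ERBB3, MYC, CCND1, DUSP6 and SPRY4 whatever their values. The text gives a selection of the list members. Where a gene was above background on no array of 1 group, its fold is written as "at least", computed from the other group's mean and the lowest signal that counted as above background on the dimmer group's arrays. A difference of the responses with such a group is given as a bound where the floor can only enlarge it and the groups that limit it were above background on all 3 arrays, and is otherwise not given. Where a gene was above background on 1 or 2 arrays of a group, the text says so, and a fold given there as "at least" takes each array at its own signal or that lowest signal, whichever was higher.

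The method was tested on simulated data in which 200 of 11345 genes were changed by a known fold. It recovered 16%, 14%, 10%, 12% and 4% of genes changed by 1.2-fold in the 5 comparisons. It recovered 92%, 86%, 80%, 80% and 62% of genes changed by 1.5-fold, and between 96% and 100% of those changed by 2-fold. Between 6 and 11 unchanged genes were called. In the data between 39.8% and 59.3% of genes passed, which makes the adjusted threshold less strict than in the simulation. The shares recovered and the unchanged genes called thus do not carry over to the data.

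Alternatives were the deposited values, quantile normalization without background correction, median scaling without quantile normalization, the offset of 16, other filters on dim probes, the mean of a gene's probes, the replicate number as a block, only the arrays compared, an intensity trend, array weights, stricter thresholds, each array left out, an estimated correlation in camera, and fry. A block for the slide was not run because the files name no slides. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the files, and matplotlib 3.10.9 drew the figures.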

Results

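Transcript levels were measured on 12 arrays of MCF10A mammary epithelial cells in 4 groups of 3. Cells grew with 10 ng/ml of EGF or 20 ng/ml of AREG, and arrays were made with the ligand present or 24 h after withdrawal. The 75th percentile of raw signal lay between 173.3 and 185.2 with EGF present, 159.3 and 165.8 after EGF withdrawal, 180 and 185.9 with AREG present, and 166.7 and 172.1 after AREG withdrawal. Between 17113 and 19991 of 48803 probes were above background on an array. The correlation of 2 arrays of 1 group was between 0.994 and 0.997, and that of arrays of different groups between 0.899 and 0.963. The number of arrays limits the precision. Changes below are on the log2 scale with the standard error (SE) of the model, n = 3 arrays per group, and 11345 genes were tested. Since nothing in the labels says that replicates were separate cultures, p-values measure the spread between arrays, which may be technical.

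The comparison of withdrawn with EGF-grown cells asks which transcripts depended on continued EGF. The 8 genes that fell furthest all serve DNA replication or mitosis. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell by 5.80 (SE 0.08). GINS2, a subunit of the replicative helicase, fell by 4.79 (SE 0.12). CDCA5, a regulator of sister chromatid cohesion, fell by 4.75 (SE 0.10), and CCNA2, cyclin A2, fell by 4.24 (SE 0.10). TOP2A, a DNA topoisomerase, CENPA, the centromeric histone variant, CDC45, a helicase component, and AURKB, a mitotic kinase, ended not well above background. They were at least 28.5-fold, 17.9-fold, 14.5-fold and 13.8-fold lower. SELENOP, which encodes the selenium carrier selenoprotein P, rose by 6.56 (SE 0.09), and MMP7, a secreted matrix protease, by 4.75 (SE 0.13). FBXO32, a FOXO-induced ubiquitin ligase subunit, rose by 4.46 (SE 0.08) and HSD11B2, which inactivates cortisol, by 4.21 (SE 0.11). Increases of 3.88 (SE 0.08) for ATP6V1B1, a proton pump subunit, 3.45 (SE 0.10) for BMF, a pro-apoptotic BCL2 relative, and 3.02 (SE 0.09) for HOPX, a homeodomain-only protein, followed. DHRS3, a retinaldehyde reductase, was at least 6.85-fold higher.

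All 28 measured genes of the mitosis list fell on EGF withdrawal (median −3.36, adjusted p = 8.88e-25, 28 adjusted over the list alone). Of 26 S phase and DNA replication genes 24 fell (median −2.13, adjusted p = 1.87e-17, 24 adjusted over the list alone). Among them was TK1, thymidine kinase, at −3.45 (SE 0.11). ERK pathway output was lower in 16 of 22 genes and higher in 1 (median −1.61, adjusted p = 2.82e-09, 17 changed when adjusted over the list alone). Within it, DUSP6, a phosphatase that inactivates ERK, fell by 3.43 (SE 0.13), and the transcription factor EGR1 fell by 3.05 (SE 0.10). CCND1, cyclin D1, fell by 2.80 (SE 0.07) and MYC, a growth-promoting transcription factor, fell by 1.78 (SE 0.09). SPRY4, a feedback inhibitor of receptor signalling, ended not well above background and was at least 2.23-fold lower. Ribosome biogenesis and MYC targets were lower in 21 of 22 genes (median −1.19, adjusted p = 1.57e-10, 21 adjusted over the list alone). LYAR, a nucleolar protein, fell by 2.78 (SE 0.09). ODC1, the first enzyme of polyamine synthesis, fell by 2.24 (SE 0.08) and NOP56, a protein of small nucleolar ribonucleoproteins, fell by 2.06 (SE 0.09). ATF4 and amino acid response genes were lower in 16 of 20 and higher in 0 (median −0.68, adjusted p = 1.14e-06, 16 adjusted over the list alone). PSAT1, an enzyme of serine synthesis, fell by 3.07 (SE 0.08) and TRIB3, a stress-induced pseudokinase, fell by 2.87 (SE 0.09).

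Genes of fatty acid synthesis fell on EGF withdrawal in 9 of 9 (median −0.62, adjusted p = 0.000164, 9 adjusted over the list alone). Cholesterol synthesis genes were lower in 13 of 18 and higher in 2 (median −0.58, adjusted p = 0.00194, 15 changed when adjusted over the list alone). ELOVL6, a fatty acid elongase, fell by 2.13 (SE 0.10). SCD, which desaturates fatty acids, fell by 1.57 (SE 0.08) and HMGCS1, an early enzyme of cholesterol synthesis, fell by 1.30 (SE 0.09). FOXO targets and quiescence genes were higher in 21 of 27 and lower in 2 (median 1.07, adjusted p = 6.57e-09, 23 changed when adjusted over the list alone). YPEL3, a growth suppressor, rose by 2.77 (SE 0.09). GABARAPL1, an autophagosome protein, rose by 2.51 (SE 0.08) and BCL6, a transcriptional repressor, by 2.20 (SE 0.08). Lysosome and autophagy genes were higher in 16 of 20 and lower in 2 (median 0.78, adjusted p = 5.74e-05, 18 changed when adjusted over the list alone). ULK1, a kinase that starts autophagy, rose by 2.28 (SE 0.10). The 9 lists named so far kept their calls with an estimated correlation in camera.

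Another 3 lists were called higher on EGF withdrawal, and none of these calls held with an estimated correlation. Basal epithelial markers were higher in 7 of 10 genes and lower in 1 (median 0.53, adjusted p = 0.0421, 8 changed when adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Their call also ended without EGF present replicate 3 (adjusted p = 0.0528) or EGF withdrawn replicate 3 (adjusted p = 0.0518). Squamous differentiation genes were higher in 8 of 17 and lower in 2 (median 0.12, adjusted p = 0.0449, 10 changed when adjusted over the list alone; adjusted p = 0.0873 with an estimated correlation). That call ended without EGF withdrawn replicate 1 (adjusted p = 0.0507) or replicate 2 (adjusted p = 0.0525), and with the replicate number as a block (adjusted p = 0.0537). Of the leukocyte markers 4 of 5 were higher (median 1.54, adjusted p = 0.00919, 4 adjusted over the list alone; adjusted p = 0.0657 with an estimated correlation). They included CD14, a lipopolysaccharide co-receptor, at 1.81 (SE 0.10), CSF1R, the receptor of a macrophage growth factor, at 1.67 (SE 0.07) and CD68, a protein of lysosomal membranes, at 1.54 (SE 0.09). The abundant leukocyte transcripts PTPRC, CD74, HLA-DRA, TYROBP and FCER1G were above background on all 3 arrays of no group.

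The other 13 lists were not called for EGF withdrawal. Of the EGF-family ligands, receptors and feedback genes 4 of 14 were higher and 6 lower (median −0.19, adjusted p = 0.542, 11 changed when adjusted over the list alone). ERBB3 and ERBB2, receptors related to the EGF receptor, rose by 1.73 (SE 0.08) and 1.29 (SE 0.08). The ligand genes HBEGF and TGFA fell by 1.77 (SE 0.13, with 2 of 3 arrays above background afterwards) and 0.52 (SE 0.09). EREG, above background on 1 of 3 arrays afterwards, was at least 1.2-fold lower. EGFR, the EGF receptor, changed by −0.25 (SE 0.08, adjusted p = 0.0165). Its dimmer probe rose by 0.58 (SE 0.12), the mean of its probes gave 0.17 (adjusted p = 0.115), and its call ended without EGF present replicate 1 (adjusted p = 0.0617). Dimmer probes of ERBB2 and ERBB3 did not pass, at −0.23 (SE 0.11, adjusted p = 0.0692) and 0.21 (SE 0.09, adjusted p = 0.0707). The EGF probe was above background on 0 arrays, and the AREG transcript was not analysed here. Medians were 0.21 for mesenchymal markers (adjusted p = 0.0665), −0.46 for glycolysis and glucose transport (0.0776), and 0.29 for interferon-stimulated genes (0.0837). With median scaling these 3 lists were called, at medians of 0.37 (adjusted p = 0.0227), −0.39 (0.0476) and 0.37 (0.00703), and mesenchymal markers also without EGF present replicate 2 (0.0436). They were 0.05 for p53 targets (0.345), 0.15 for luminal markers (0.52), −0.11 for interleukin 1 and NF-kB targets (0.52), and 0.18 for hypoxia response (0.542). The last were 0.05 for fibroblast and stromal markers (0.542), −0.10 for endothelial markers (0.542), −0.04 for invasion and proteolysis (0.559) and 0.16 for adhesion and hemidesmosome (0.646). NRF2 targets had a median of −0.30, a mean of 0.11 and a lower direction in camera (adjusted p = 0.755).

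Over all genes, 6731 of 11345 changed on EGF withdrawal (59.3%), 3536 higher and 3195 lower. A fold of at least 2 was reached by 527 higher and 687 lower genes, and at least 4 by 60 and 166. The 2 groups of arrays did not overlap for 62.9% of genes, against 10% by chance.

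**Figure D1:**
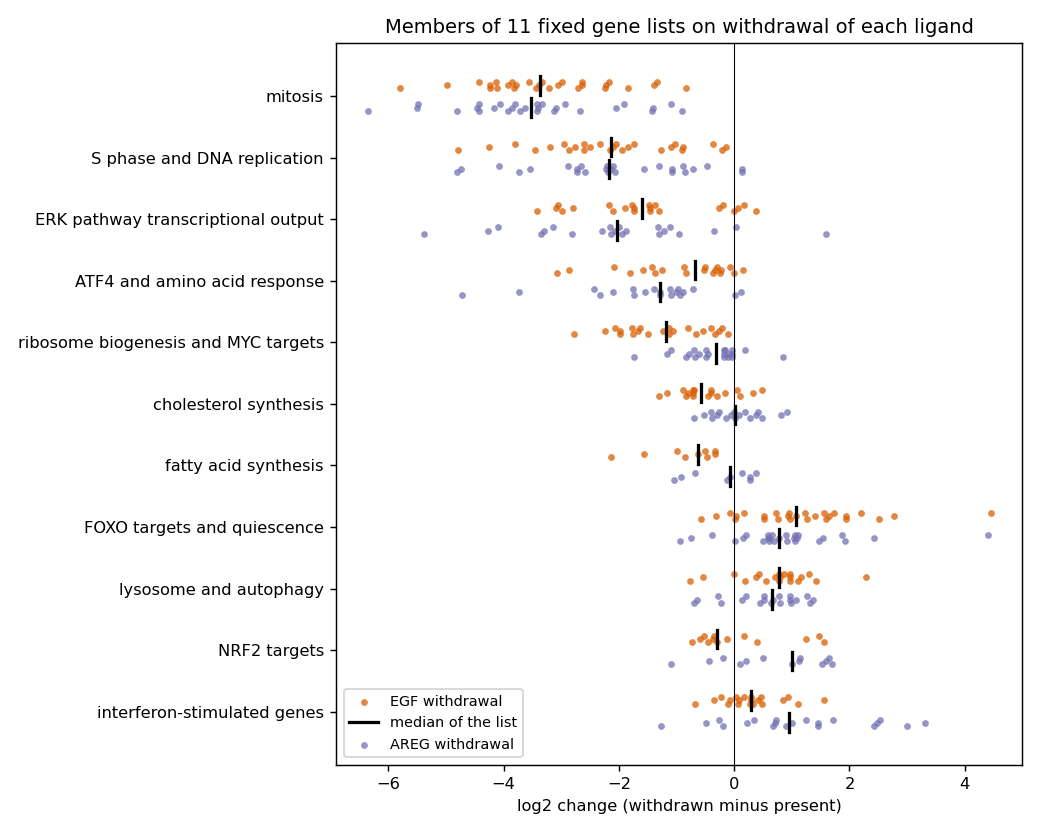
Log2 change of each measured member of 11 fixed gene lists on EGF withdrawal (orange) and AREG withdrawal (purple); each point is 1 gene and each black bar the median of the list. All 28 mitosis genes lay under 0 for both ligands, while the medians of ribosome biogenesis genes were −1.19 for EGF and −0.32 for AREG.

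The comparison of withdrawn with AREG-grown cells asks the same of AREG. UBE2C fell by 6.36 (SE 0.08), and CDC20, an activator of the anaphase-promoting complex, fell by 5.49 (SE 0.08). CDCA5 fell by 4.92 (SE 0.10) and CDC45 fell by 4.81 (SE 0.08, with 2 of 3 arrays above background afterwards). TOP2A, not well above background afterwards, was at least 38.7-fold lower. Outside cell division, PHLDA1, an ERK-induced gene, fell by 5.38 (SE 0.10, with 2 of 3 arrays above background afterwards) and MT1G, a metal-binding metallothionein, fell by 4.95 (SE 0.09). THBS1, the secreted glycoprotein thrombospondin 1, was at least 36.7-fold lower, above background on 1 of 3 arrays. FBXO32 rose by 4.40 (SE 0.08). GPNMB, a glycoprotein of lysosomes, had been above background on 1 of 3 arrays and was at least 14.1-fold higher. IGFBP3, which binds insulin-like growth factors, rose by 3.52 (SE 0.10) and WNT4, a secreted signalling protein, by 3.49 (SE 0.09). ALDH3A1, an aldehyde dehydrogenase, rose by 3.36 (SE 0.13), IFIT3, an interferon-induced protein, by 3.31 (SE 0.10) and KLK8, a secreted serine protease, by 3.20 (SE 0.09). UGT1A7, a glucuronosyltransferase whose probe may detect related enzymes, had not been well above background and was at least 8.3-fold higher. A dimmer probe of FBXO32 did not pass, at 0.28 (SE 0.12, adjusted p = 0.0672).

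Mitosis genes were lower in 28 of 28 on AREG withdrawal (median −3.53, adjusted p = 6.6e-28, 28 adjusted over the list alone), and S phase and DNA replication genes in 24 of 26 (median −2.17, adjusted p = 6.38e-18, 24 adjusted over the list alone). ERK pathway output was lower in 20 of 22 and higher in 1 (median −2.04, adjusted p = 4.37e-14, 21 changed when adjusted over the list alone). DUSP6, above background on 1 of 3 arrays afterwards, was at least 17.5-fold lower, and IER3, an immediate-early gene, fell by 4.09 (SE 0.09). EGR1 fell by 3.36 (SE 0.10), MYC fell by 1.30 (SE 0.09) and CCND1 fell by 0.95 (SE 0.07). SPRY4 was at least 3.64-fold lower. Of the ATF4 and amino acid response genes 18 of 20 were lower and 0 higher (median −1.28, adjusted p = 6.08e-12, 18 adjusted over the list alone). TRIB3 fell by 4.72 (SE 0.09) and ASNS, asparagine synthetase, fell by 3.73 (SE 0.09). MTHFD2, a mitochondrial folate enzyme, fell by 2.43 (SE 0.09) and DDIT3, a stress-induced transcription factor, fell by 2.32 (SE 0.09). Ribosome biogenesis and MYC targets were lower in 11 of 22 and higher in 1 (median −0.32, adjusted p = 0.00243, 12 changed when adjusted over the list alone). LYAR was at −1.74 (SE 0.09) and NOP56 at −1.17 (SE 0.09).

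Interferon-stimulated genes were higher in 15 of 20 and lower in 3 on AREG withdrawal (median 0.95, adjusted p = 7.03e-06, 18 changed when adjusted over the list alone). IFIT2, which binds viral RNA, rose by 2.99 (SE 0.15), ISG15, a ubiquitin-like modifier, by 2.53 (SE 0.11) and IFI44, an interferon-induced protein, by 2.47 (SE 0.09). FOXO targets and quiescence genes were higher in 21 of 27 and lower in 3 (median 0.77, adjusted p = 1.02e-07, 25 changed when adjusted over the list alone). GABARAPL1 rose by 2.42 (SE 0.08). Lysosome and autophagy genes were higher in 14 of 20 and lower in 4 (median 0.65, adjusted p = 0.000745, 18 changed when adjusted over the list alone). ULK1 rose by 1.37 (SE 0.10) and CTSD, a lysosomal protease, by 1.27 (SE 0.08). Basal epithelial markers were higher in 8 of 10 and lower in 2 (median 1.08, adjusted p = 0.00151, 10 changed when adjusted over the list alone). The keratins KRT15 and KRT16 rose by 2.66 (SE 0.09) and 2.37 (SE 0.08), while KRT14 fell by 1.19 (SE 0.09). KRT15 had a mean of 15.71 after AREG withdrawal and 15.72 after EGF withdrawal, near the highest normalized signal of 15.87, so that saturation may limit its changes. NRF2 targets were higher in 8 of 13 and lower in 3 (median 1.01, adjusted p = 0.00476, 12 changed when adjusted over the list alone). TXNRD1, thioredoxin reductase, rose by 1.70 (SE 0.09) and ABCC2, an efflux transporter, by 1.52 (SE 0.09, with 2 of 3 arrays above background before). The 10 lists named so far for AREG withdrawal kept their calls with an estimated correlation.

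EGF-family ligands, receptors and feedback genes were lower in 8 of 14 and higher in 2 on AREG withdrawal (median −0.37, adjusted p = 0.0201, 10 changed when adjusted over the list alone; adjusted p = 0.0541 with an estimated correlation). HBEGF fell by 4.24 (SE 0.13), ERRFI1, an inhibitor of the EGF receptor, fell by 1.74 (SE 0.10) and TGFA fell by 1.59 (SE 0.09). ERBB3 rose by 1.47 (SE 0.08) and ERBB2 by 0.66 (SE 0.08, with a dimmer probe at −0.11, adjusted p = 0.406). The value for EGFR was −0.29 (SE 0.08, adjusted p = 0.00643), which ended with the mean of its probes (−0.02, adjusted p = 0.892), and EREG, not well above background after AREG withdrawal, did not pass (adjusted p = 0.194). Invasion and extracellular proteolysis genes were lower in 9 of 16 and higher in 4 (median −0.42, adjusted p = 0.0333, 14 changed when adjusted over the list alone; adjusted p = 0.0676 with an estimated correlation). SERPINE2, a protease inhibitor, fell by 3.95 (SE 0.09). Among lists that were not called, squamous differentiation had a median of 0.25 (adjusted p = 0.0557) and adhesion and hemidesmosome one of −0.40 (0.068). Others were leukocyte markers at 0.23 (0.308), fatty acid synthesis at −0.08 (0.506) and cholesterol synthesis at 0.01 (0.874). The squamous list became called with the deposited values (adjusted p = 0.0493), without background correction (0.0493), and without AREG withdrawn replicate 1 (0.0447) or 2 (0.0392) or EGF present replicate 2 (0.0452).

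Over all genes, 6110 of 11345 changed on AREG withdrawal (53.9%), 3157 higher and 2953 lower. A fold of at least 2 was reached by 428 higher and 647 lower genes, and at least 4 by 46 and 212. Arrays of the 2 groups did not overlap for 59.5% of genes, against 10% by chance.

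Growth in the 2 ligands was compared to ask whether cells kept in AREG differ from cells kept in EGF. With ligand present, CA12, a membrane carbonic anhydrase, was above background on 2 of 3 arrays in EGF and at least 50.2-fold higher in AREG. KRTDAP, a keratinocyte differentiation-associated protein, was higher by 4.72 (SE 0.09). IL1A, the cytokine interleukin 1 alpha, was higher by 4.70 (SE 0.09) and RTTN, a centriole protein, by 4.12 (SE 0.09). KRT14, a keratin of basal cells, was not well above background in EGF and at least 15.3-fold higher in AREG. INPP5D, a lipid phosphatase, was above background on 1 of 3 arrays in EGF and at least 13.9-fold higher. GSDME, a pore-forming gasdermin, and BEX3 were higher by 3.92 (SE 0.08) and 3.67 (SE 0.08). A dimmer probe of BEX3 did not pass, at 0.19 (SE 0.10, adjusted p = 0.138). Lower in AREG were MGP, an inhibitor of calcification, at −4.75 (SE 0.09), MUC1, a mucin of luminal cells, at −4.65 (SE 0.08) and CST6, a protease inhibitor, at −4.56 (SE 0.09). CD163L1, a scavenger receptor, was at −4.15 (SE 0.08). The secreted proteases KLK6 and KLK7 had changes of −4.05 (SE 0.08) and −3.96 (SE 0.09). KYNU, an enzyme of tryptophan breakdown, was at −3.68 (SE 0.08) and the keratin KRT80 at −3.67 (SE 0.14).

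With ligand present, 3 of 25 lists were called. ATF4 and amino acid response genes were higher in AREG in 18 of 20 (median 0.94, adjusted p = 1.4e-12, 18 adjusted over the list alone). They included DDIT3 at 2.16 (SE 0.09), the amino acid transporter SLC7A5 at 1.97 (SE 0.09) and PHGDH, an enzyme of serine synthesis, at 1.60 (SE 0.08). Luminal mammary markers were lower in 7 of 10 and higher in 1 (median −0.64, adjusted p = 0.00132, 9 changed when adjusted over the list alone). KRT8, a keratin of luminal cells, was at −3.66 (SE 0.09). Both calls held with an estimated correlation. Interferon-stimulated genes were higher in 12 of 20 and lower in 2 (median 0.32, adjusted p = 0.0326, 14 changed when adjusted over the list alone; adjusted p = 0.114 with an estimated correlation). ERK pathway output was higher in 13 of 22 and lower in 5 (median 0.42, 19 changed when adjusted over the list alone), which missed the threshold (adjusted p = 0.0506). It passed with the replicate block (0.0426), the deposited values (0.0409), no background correction (0.0409), median scaling (0.0416), and without AREG present replicate 1 (0.0424), AREG withdrawn replicate 1 (0.048) or 2 (0.0466), or EGF present replicate 2 (0.039) or 3 (0.042). Basal epithelial markers had a median of 0.72 (adjusted p = 0.0674, or 0.0479 without AREG present replicate 1). Adhesion and hemidesmosome genes, not called either, had a median of 0.43 (adjusted p = 0.0674).

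Of the genes given whatever their values, HBEGF was higher in AREG with ligand present by 2.59 (SE 0.13), EGFR by 1.12 (SE 0.08), MYC by 1.05 (SE 0.09), SPRY4 by 0.66 (SE 0.09) and TGFA by 0.60 (SE 0.09). ERBB3, ERBB2 and CCND1 were lower, at −1.30 (SE 0.08), −0.53 (SE 0.08) and −0.25 (SE 0.07). Dimmer probes of ERBB2 and SPRY4 did not pass, at −0.01 (SE 0.11, adjusted p = 0.967) and 0.04 (SE 0.11, adjusted p = 0.781). DUSP6 was higher by 0.43 (SE 0.13, adjusted p = 0.0139), a call that ended without AREG present replicate 3 (adjusted p = 0.0796) or EGF present replicate 2 (0.0732) and with an offset of 16 (0.0769). EREG was at −0.26 (SE 0.11, adjusted p = 0.0652, with 2 of 3 arrays above background in AREG), and passed without EGF withdrawn replicate 2 (0.0374) or 3 (0.044), with array weights (0.0435), with only the arrays compared (0.0391) and with median scaling (0.0312). In all, 4751 of 11345 genes differed (41.9%), 2507 higher and 2244 lower in AREG, of which 329 and 242 by a fold of at least 2. Arrays of the 2 groups did not overlap for 53.3% of genes, against 10% by chance.

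After withdrawal, BEX3 was higher in cells grown in AREG by 5.02 (SE 0.08) and FABP5, a fatty acid-binding protein, by 4.43 (SE 0.09). CA12, KRTDAP and TIMP3, an inhibitor of matrix proteases, were above background on 1 of 3 arrays after EGF withdrawal. They were at least 56.7-fold, 30.9-fold and 18.4-fold higher after AREG withdrawal. FGFR3, a fibroblast growth factor receptor, UGT1A6, a glucuronosyltransferase, and RAB7B, a small GTPase, were not well above background after EGF withdrawal. They were at least 28.9-fold, 25-fold and 19.5-fold higher after AREG withdrawal. A dimmer FGFR3 probe did not pass, at 0.06 (SE 0.11, adjusted p = 0.692). SELENOP was lower by a log2 change of −6.72 (SE 0.09), ATP6V1B1 of −5.50 (SE 0.08), CST6 of −5.44 (SE 0.09) and HSD11B2 of −5.34 (SE 0.11). DEFB1, an antimicrobial peptide, was at −4.94 (SE 0.09), MGP at −4.62 (SE 0.09), MUC1 at −4.61 (SE 0.08) and FOXQ1, a transcription factor, at −4.56 (SE 0.08).

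Ribosome biogenesis and MYC targets were higher in 21 of 22 genes after AREG than after EGF withdrawal (median 0.83, adjusted p = 1.31e-09, 21 adjusted over the list alone). RRS1, a ribosome assembly factor, was at 1.40 (SE 0.12) and SRM, spermidine synthase, at 1.27 (SE 0.09). Interferon-stimulated genes were higher in 16 of 20 and lower in 2 (median 0.89, adjusted p = 1.91e-06, 18 changed when adjusted over the list alone). IFIT3 was at 3.21 (SE 0.10, with 2 of 3 arrays above background after EGF withdrawal) and ISG15 at 2.87 (SE 0.11). Higher were also 6 of 10 basal markers with 1 lower (median 1.09, adjusted p = 0.00421, 7 changed when adjusted over the list alone) and 8 of 9 fatty acid synthesis genes with 1 lower (median 0.79, adjusted p = 0.00472, 9 changed when adjusted over the list alone). The same held for 12 of 18 cholesterol synthesis genes with 2 lower (median 0.39, adjusted p = 0.00472, 15 changed when adjusted over the list alone). SQLE, squalene epoxidase, was higher by 1.99 (SE 0.09) and FASN, fatty acid synthase, by 1.18 (SE 0.08). Glycolysis and glucose transport genes were higher in 14 of 20 and lower in 2 (median 0.46, adjusted p = 0.00555, 16 changed when adjusted over the list alone). NRF2 targets were higher in 9 of 13 and lower in 2 (median 0.49, adjusted p = 0.00555, 11 changed when adjusted over the list alone), with GCLC, an enzyme of glutathione synthesis, at 1.55 (SE 0.09).

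Luminal mammary markers were lower after AREG withdrawal in 7 of 10 and higher in 1 (median −0.82, adjusted p = 0.000804, 9 changed when adjusted over the list alone). So were lysosome and autophagy genes in 13 of 20, with 2 higher (median −0.32, adjusted p = 0.00472, 15 changed when adjusted over the list alone). Invasion and proteolysis genes were lower in 9 of 16 and higher in 3 (median −0.27, adjusted p = 0.00555, 12 changed when adjusted over the list alone). MMP7 was at −4.01 (SE 0.13) and KRT19, a keratin of luminal cells, at −2.47 (SE 0.10). Those 10 calls held with an estimated correlation. Leukocyte markers were lower in 3 of 5 (median −0.96, adjusted p = 0.0165, 3 adjusted over the list alone; adjusted p = 0.0754 with an estimated correlation). FOXO targets and quiescence genes were lower in 15 of 27 and higher in 4 (median −0.22, adjusted p = 0.0465, 19 changed when adjusted over the list alone; adjusted p = 0.0754 with an estimated correlation). Their call ended with the replicate block (adjusted p = 0.0536), median scaling (median −0.13, adjusted p = 0.1), and without AREG withdrawn replicate 1 (0.0561) or 3 (0.0592) or EGF withdrawn replicate 3 (0.0671). ATF4 and amino acid response genes were higher in 10 of 20 and lower in 5 (median 0.19, adjusted p = 0.0465, 15 changed when adjusted over the list alone; adjusted p = 0.0757 with an estimated correlation). Theirs ended with the replicate block (adjusted p = 0.0536) and without AREG withdrawn replicate 1 (median 0.11, adjusted p = 0.0561), AREG present replicate 2 (0.05) or 3 (0.0502) or EGF withdrawn replicate 3 (0.0654). Mitosis genes were not called (median −0.06, adjusted p = 0.195), and with median scaling were (median −0.15, adjusted p = 0.0295). Among them, TOP2A, CENPA and AURKB were not well above background after either withdrawal, which limits that comparison.

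After withdrawal CCND1 was higher in AREG-grown cells by 1.60 (SE 0.07), MYC by 1.53 (SE 0.09) and EGFR by 1.08 (SE 0.08). ERBB3, ERBB2 and TGFA were lower, at −1.56 (SE 0.08), −1.16 (SE 0.08) and −0.48 (SE 0.09). Dimmer probes of EGFR, ERBB3 and ERBB2 did not pass, at 0.19 (SE 0.12, adjusted p = 0.218), −0.16 (SE 0.09, adjusted p = 0.179) and 0.12 (SE 0.11, adjusted p = 0.395). DUSP6, above background on 1 of 3 arrays after AREG withdrawal, was at least 1.21-fold lower (adjusted p = 0.0134), a call that ended without AREG withdrawn replicate 2 (adjusted p = 0.0828) or EGF withdrawn replicate 3 (0.056). HBEGF was at 0.12 (SE 0.13, adjusted p = 0.485), or at 0.29 (adjusted p = 0.0424) without EGF withdrawn replicate 1. EREG, not well above background after AREG withdrawal, did not pass (adjusted p = 0.723). SPRY4 was not well above background after either withdrawal. In all, 5625 of 11345 genes differed (49.6%), 2838 higher and 2787 lower, of which 483 and 507 by a fold of at least 2. Arrays of the 2 groups did not overlap for 53.6% of genes, against 10% by chance.

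**Figure D2:**
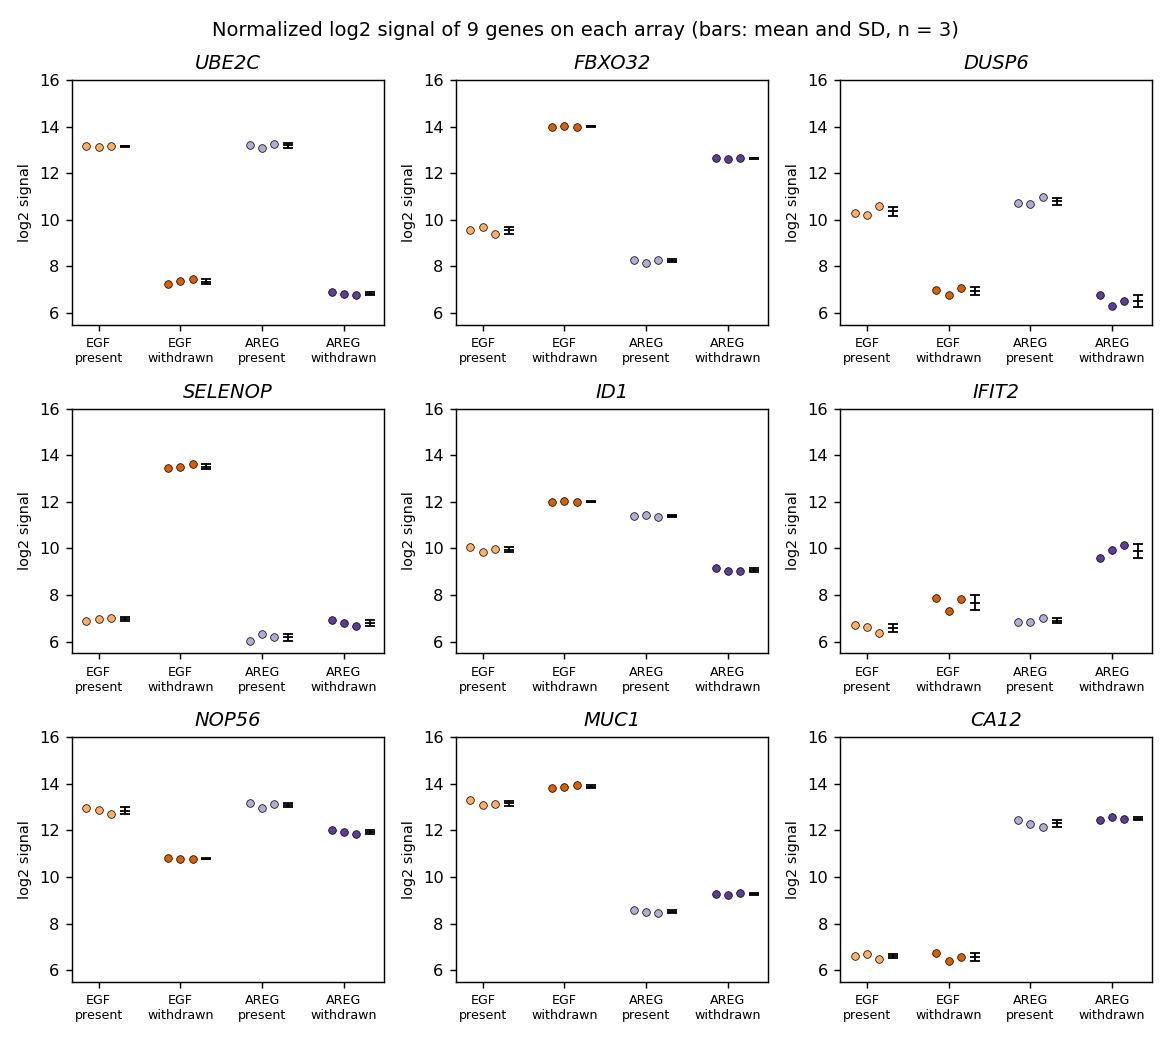
Normalized log2 signal of 9 genes on each of the 12 arrays, with the mean and SD of each group of 3 beside its points. UBE2C had means of 13.14 and 13.19 with EGF and AREG present and of 7.34 and 6.83 after their withdrawal, while CA12 and MUC1 differed between the ligands before and after withdrawal.

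The withdrawal responses were then compared with each other, to ask whether cells answer the loss of AREG as they answer the loss of EGF. Many genes moved alike, with 1976 higher and 1870 lower in both, against 984 and 832 if the calls were independent. In opposite directions were 547, against 1809. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.701 and a Spearman rho of 0.596. A fold of at least 2 in opposite directions was found for 7 genes, all higher after EGF withdrawal and lower after AREG withdrawal. ID1, an inhibitor of differentiation, rose by 2.06 (SE 0.08) and fell by 2.33 (SE 0.08). CRIP2, a LIM domain protein, rose by 2.64 (SE 0.08) and fell by 1.29 (SE 0.08). CYP1B1, a cytochrome P450, rose by 1.71 (SE 0.10) and fell by 1.57 (SE 0.10). The others were SAT1, FOXQ1, VASN and JUN, of which VASN and JUN were picked after their values were seen.

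**Figure D3:**
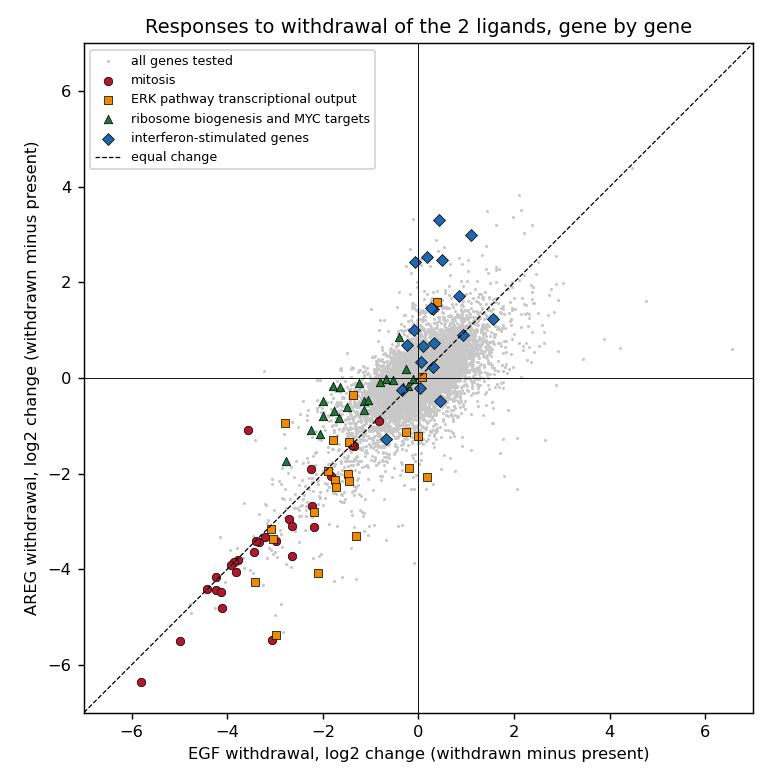
Log2 change on AREG withdrawal (y axis) against that on EGF withdrawal (x axis) for 11345 genes, with 4 gene lists in colour and a dashed line of equal change. The vertical offset from the line, positive above it, is the difference of the responses. Its median was −0.19 for mitosis, −0.54 for ERK output, 0.86 for ribosome biogenesis and 0.73 for interferon-stimulated genes. Some mitosis genes were not well above background after either withdrawal.

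Of the 8 genes with the highest fitted difference (AREG response minus EGF response), FABP5 was at 3.37 (SE 0.13), RASL11B, a small GTPase, at 2.59 (SE 0.18, with 2 of 3 arrays above background after EGF withdrawal) and PTTG1, securin, at 2.48 (SE 0.15). UGT1A7, IFIT3, FABP4, another fatty acid-binding protein, PLAAT4, a phospholipase, and OASL, an antiviral protein, were not well above background in at least 1 group, which left neither a value nor a bound for their difference. The same held for SELENOP among the 8 genes with the lowest fitted difference. The others were ID1 at −4.39 (SE 0.11), CRIP2 at −3.94 (SE 0.11), SAT1, an enzyme of polyamine breakdown, at −3.85 (SE 0.11), CCN2, a matricellular growth factor, at −3.78 (SE 0.14), HSD11B2 at −3.59 (SE 0.15), FOXQ1 at −3.31 (SE 0.11) and CYP1B1 at −3.29 (SE 0.14).

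Of 25 lists 17 were called for the difference, 9 of them also with an estimated correlation. Ribosome biogenesis and MYC targets had a positive difference in 19 of 22 genes (median difference 0.86, adjusted p = 3.43e-10, 19 adjusted over the list alone). Of these, RRS1 was at 1.61 (SE 0.17) and NOP16, a nucleolar protein, at 1.46 (SE 0.11). The difference was positive in 11 of 18 cholesterol synthesis genes and negative in 1 (median 0.53, adjusted p = 0.000216, 14 changed when adjusted over the list alone), and in 12 of 20 interferon-stimulated genes and negative in 2 (median 0.73, adjusted p = 0.00026, 15 changed when adjusted over the list alone). It was also positive in 8 of 9 fatty acid synthesis genes and negative in 1 (median 0.71, adjusted p = 0.000636, 9 changed when adjusted over the list alone) and in 8 of 13 NRF2 targets and negative in 1 (median 0.54, adjusted p = 0.000998, 9 changed when adjusted over the list alone). It was negative in 10 of 16 invasion and proteolysis genes and positive in 1 (median −0.55, adjusted p = 0.000379, 11 changed when adjusted over the list alone) and in 8 of 14 EGF-family genes (median −0.52, adjusted p = 0.00323, 8 adjusted over the list alone). It was negative in 12 of 22 ERK output genes and positive in 4 (median −0.54, adjusted p = 0.00323, 18 changed when adjusted over the list alone) and in 13 of 20 ATF4 and amino acid response genes and positive in 5 (median −0.69, adjusted p = 0.00323, 18 changed when adjusted over the list alone). PHLDA1 was at −2.40 (SE 0.15), HBEGF at −2.48 (SE 0.18) and DDIT3 at −2.47 (SE 0.13). PHLDA1 was above background on 2 of 3 arrays after AREG withdrawal. HBEGF was above background on 2 of 3 arrays after EGF withdrawal, where a lower level would shrink its difference.

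Calls for the other 8 lists did not hold with an estimated correlation. Medians were −0.38 for p53 targets (10 of 19 lower and 1 higher, adjusted p = 0.0146; adjusted p = 0.0878 with an estimated correlation), where GDF15, a stress-induced cytokine, was at −2.38 (SE 0.18). They were −0.33 for adhesion and hemidesmosome (8 of 16 lower and 1 higher, adjusted p = 0.0164; adjusted p = 0.0511 with an estimated correlation), where ITGB4, an integrin of hemidesmosomes, was at −1.66 (SE 0.14). Basal markers had a median of 0.20 (4 of 10 higher and 1 lower, adjusted p = 0.0319; adjusted p = 0.102 with an estimated correlation) and glycolysis genes one of 0.32 (9 of 20 higher and 4 lower, adjusted p = 0.0319; adjusted p = 0.0623 with an estimated correlation). FOXO targets had a median of −0.15 (12 of 27 lower and 2 higher, adjusted p = 0.0319; adjusted p = 0.062 with an estimated correlation), and median scaling ended that call (median −0.09, adjusted p = 0.0531). Mitosis genes had a median of −0.19 (9 of 28 lower and 1 higher, adjusted p = 0.0319; adjusted p = 0.062 with an estimated correlation), with no call without AREG present replicate 3 (adjusted p = 0.0507). Their median and call include genes not well above background after either withdrawal, among them TOP2A, CENPA and AURKB, whose differences are not measured. Leukocyte markers had a median of −0.20 (2 of 5 lower, adjusted p = 0.0416; adjusted p = 0.112 with an estimated correlation). No call was made for them with median scaling (0.0527) or without EGF withdrawn replicate 1 (0.0588), AREG withdrawn replicate 1 (0.0603) or AREG present replicate 3 (0.0512). Mesenchymal markers had a median of −0.17 (4 of 12 lower, adjusted p = 0.0437; adjusted p = 0.21 with an estimated correlation), and no call with median scaling (median −0.11, adjusted p = 0.0588) or without EGF withdrawn replicate 1 (0.0647), AREG present replicate 2 (0.0559) or 3 (0.0558), or EGF present replicate 3 (median −0.11, adjusted p = 0.0697). Adjusted over the list alone, changed genes numbered 13 for p53 targets, 9 for adhesion, 5 for basal markers, 13 for glycolysis, 15 for FOXO targets, 10 for mitosis, 2 for leukocyte markers and 4 for mesenchymal markers.

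Differences of single genes given whatever their values were 1.85 (SE 0.10) for CCND1, 0.48 (SE 0.12) for MYC, −0.84 (SE 0.18) for DUSP6 (with 1 of 3 arrays above background after AREG withdrawal) and −1.07 (SE 0.13) for TGFA. ERBB2 was at −0.63 (SE 0.11, adjusted p = 0.000305), or at −0.25 (adjusted p = 0.0687) with the mean of its probes. EGFR at −0.05 (SE 0.12, adjusted p = 0.792) did not pass. SPRY4, not well above background after either withdrawal, and EREG, not well above background after AREG withdrawal, had neither a value nor a bound. ERBB3 was at −0.26 (SE 0.12, adjusted p = 0.0925), and passed with the deposited values (0.0302), without background correction (0.0302) and without AREG withdrawn replicate 3 (0.0491). In all, 4510 of 11345 genes differed in response (39.8%), 2173 with a positive and 2337 with a negative difference, and 694 by a fold of at least 2. For 424 of the 4510, 111 of them among the 694, a group not above background left no value or bound, and for 72 it left a bound.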

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

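Among the tests below, those of residual correlation and of leukocyte transcripts were chosen after the result was seen, and the other tests before. Camera after median scaling, which enters the normalization test of interferon-stimulated genes, was added after the data were seen.

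A test of the difference itself set apart the withdrawal responses to the 2 ligands in 4510 genes. Of 100 drawn splits of the ligand labels within present and within withdrawn arrays, 2 gave as many genes, the real one included. Such splits test only whether the ligand labels matter at all. Their answer to that holds if the arrays are independent, which the labels do not state. A split that mixes the ligands adds the ligand difference to the spread within groups, which lowers its count. Splits of this kind therefore cannot decide whether the difference of the responses arose by chance. If the arrays of a group repeated 1 RNA, chance differences between cultures would not be excluded either. The other split with as many genes exchanges the ligand labels of all withdrawn arrays (5771 genes). It measures the sum of the ligand differences before and after withdrawal and so follows a structure of the samples. The highest of the remaining splits gave 2683 genes.

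For the pairwise comparisons, 1 of the 10 possible splits of 6 arrays gave as many genes as the real one, namely the real one itself. Real counts were 6731, 6110, 4751 and 5625 for EGF withdrawal, AREG withdrawal, ligand present and ligand withdrawn. The highest count of the other splits was 0 with limma after Benjamini-Hochberg adjustment, and 298, 307, 286 and 483 genes at an unadjusted p under 0.05, against 7115, 6646, 5518 and 6218 for the real splits. Each of the other splits mixes the 2 groups, which adds their difference to the spread within groups and lowers the count. The gap between these counts and the real ones therefore does not measure chance. Splits of 6 arrays are also too few for a share under 0.05.

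A large share of all genes passed the threshold in each comparison, between 39.8% and 59.3%. If the 3 arrays of a group repeated 1 RNA, their spread would be technical, and genes of 1 process would not vary together within groups. The median pairwise correlation of residuals over 54 mitosis and S phase genes was −0.000908, at percentile 45.9 of 1000 random lists matched on signal, whose 95th percentile was 0.0263. That value is consistent with technical repeats, in which case the p-values would not measure variation between cultures. Separate cultures that happened to vary little remain open, as does the ligand as a biological cause of the changes.

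Ribosome biogenesis genes fell more on EGF than on AREG withdrawal, with a median difference of 0.86. Arrays made after EGF withdrawal had the lowest overall signal, so normalization could produce such a difference. Under 3 other normalizations the lowest median was 0.84 and the highest 1.03, which argues against background correction or quantile normalization as the source. The deposited values and quantile normalization without background correction are nearly the same, both at 0.84, and do not count separately. All 3 bring the arrays to a common centre, so that a true fall in overall transcript level was not tested. A difference shared by all genes of like brightness would give random lists matched on signal the same median, yet the list lay at percentile 100 of 10000 lists, whose highest median was 0.43. The ligand and its dose stay open as biological explanations and were not tested.

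Interferon-stimulated genes rose on AREG withdrawal, with a median of 0.95. RNA of leukocytes could bring such transcripts, but 0 of 5 abundant leukocyte transcripts were above background on all 3 AREG withdrawn arrays, with mean log2 signals from 6.16 (TYROBP) to 6.61 (FCER1G) against a threshold of 6.62. Of the 5 leukocyte markers tested as a list, 2 rose on AREG withdrawal, CSF1R by 1.56 (SE 0.07) and CD14 by 0.64 (SE 0.10). In the same list 1 marker, CD68, fell by 0.49 (SE 0.09). With any 1 of the 12 arrays left out, the lowest median was 0.89 and the highest 1, which argues against a single array. Normalization of arrays with a lower signal could also raise such a list. Under 3 other normalizations the lowest median was 0.83 and the highest adjusted p of camera 8.42e-06. These values argue against background correction or quantile normalization as the source. Among the 3, the deposited values and quantile normalization without background correction are nearly the same, and all 3 bring the arrays to a common centre. A response of the cells to the loss of AREG remains as a hypothesis, found and tested on the same data.

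Camera called 17 gene lists for the difference of the responses. Of these, 8 lost their call with an estimated correlation, namely adhesion (adjusted p = 0.0511), mitosis (adjusted p = 0.062), FOXO targets (adjusted p = 0.062), glycolysis (adjusted p = 0.0623), p53 targets (adjusted p = 0.0878), basal markers (adjusted p = 0.102), leukocyte markers (adjusted p = 0.112) and mesenchymal markers (adjusted p = 0.21). Positive were the medians of ribosome biogenesis and MYC targets (0.86), interferon-stimulated genes (0.73), fatty acid synthesis (0.71), NRF2 targets (0.54), cholesterol synthesis (0.53), glycolysis (0.32) and basal markers (0.20). Negative were those of ATF4 and amino acid response (−0.69), invasion and proteolysis (−0.55), ERK output (−0.54), EGF-family genes (−0.52), p53 targets (−0.38), adhesion (−0.33), leukocyte markers (−0.20), mitosis (−0.19), mesenchymal markers (−0.17) and FOXO targets (−0.15).

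Among single genes, responses to AREG withdrawal exceeded those to EGF withdrawal, on the signed log2 scale, in FABP5 (3.37), RASL11B (2.59), PTTG1 (2.48), ISG15 (2.36), KRT15 (2.24), IFI44 (1.98), IFIT2 (1.89), CCND1 (1.85) and KRT16 (1.72). Smaller positive differences were those of RRS1 (1.61), NOP16 (1.46), ELOVL6 (1.45), ALDH3A1 (1.39), IGFBP3 (1.37), ABCC2 (1.35), ODC1 (1.15), LYAR (1.03), PSAT1 (0.96), NOP56 (0.90), CTSD (0.84), KLK8 (0.82), HMGCS1 (0.77), SCD (0.52) and MYC (0.48). KRT15 and KRT16 had means of 15.72 and 15.60 after EGF withdrawal, near the highest normalized signal of 15.87, so that saturation was not excluded as a limit on their EGF responses. RASL11B after EGF withdrawal, IFIT2 with EGF present and ABCC2 with AREG present were above background on 2 of 3 arrays. A lower level there would shrink the difference of IFIT2 and enlarge those of RASL11B and ABCC2. A dimmer KLK8 probe was at −0.10 (adjusted p = 0.598).

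Negative differences were those of ID1 (−4.39), CRIP2 (−3.94), SAT1 (−3.85), CCN2 (−3.78), HSD11B2 (−3.59), FOXQ1 (−3.31), CYP1B1 (−3.29), ATP6V1B1 (−3.06), VASN (−3.05), JUN (−2.61), HBEGF (−2.48), THBS1 (−2.48), DDIT3 (−2.47), CDC20 (−2.43), PHLDA1 (−2.40), GDF15 (−2.38) and CD68 (−2.03), of which HBEGF was above background on 2 of 3 arrays after EGF withdrawal. Further ones were IER3 (−1.98), MT1G (−1.95), TRIB3 (−1.85), ERRFI1 (−1.66), ITGB4 (−1.66), ASNS (−1.64), SERPINE2 (−1.28), MTHFD2 (−1.18), CD14 (−1.16), TGFA (−1.07) and HOPX (−1.04), while DHRS3 had a bound, a difference of −1.15 or lower. Under 1 log2 unit were ULK1 (−0.91), YPEL3 (−0.90), DUSP6 (−0.84), BCL6 (−0.66), ERBB2 (−0.63), TK1 (−0.63) and UBE2C (−0.56). TK1, DUSP6 and THBS1 were above background on 1 of 3 arrays after AREG withdrawal, where a lower level would only enlarge their difference, and PHLDA1 on 2 of 3. For HBEGF, a lower level after EGF withdrawal would instead shrink the difference. UGT1A7, IFIT3, FABP4, PLAAT4, OASL, WNT4, GPNMB, SELENOP, MMP7, BMF, KRT14, SPRY4, CDC45 and TOP2A passed the test of the difference but were not well above background in at least 1 group, which left neither a value nor a bound. A dimmer UBE2C probe went the other way, at 0.39 (SE 0.13, adjusted p = 0.0239).

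Probes without a gene name, which no comparison above uses, passed the threshold in 1264 of 3803 cases for EGF withdrawal, 1037 for AREG withdrawal, 704 with ligand present, 948 after withdrawal and 667 for the difference of the responses.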

How the results depend on the processing

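Alternatives chosen after seeing the data were the offset of 16, a background tail of 0.001 and camera after median scaling. Leaving out each array gave between 6263 and 6751 changed genes for EGF withdrawal, 5643 and 6173 for AREG withdrawal, 4129 and 4839 with ligand present, 5185 and 5583 after withdrawal, and 4016 and 4281 for the difference. In the comparisons for which an array's removal leaves 2 arrays in a group, their spread is pooled with that of the other groups. With the replicate number as a replicate block the counts were 6731, 6102, 4728, 5609 and 4467, 563 of 563 gene results kept direction and side of the threshold, and so did 121 of 125 list results. Replicate numbers showed no shared effect, since deviations from group means correlated by −0.027 to 0.073 between arrays of 1 number. That does not exclude that arrays of 1 number were made together. Over the other alternatives except a fold minimum, counts stayed between 5604 and 7308, 4938 and 6636, 3454 and 5177, 4408 and 5723, and 3108 and 4648. A fold of at least 2 left 1214, 1075, 571, 990 and 694 genes, since that threshold by construction removes small changes. Under each scaling the median change of all genes stayed within 0.075 of 0. Each scaling brings the arrays to a common centre, so that this median could not show a shift common to all genes.

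With fry, which does not compare a list with other genes, 23 lists were called for EGF withdrawal, 22 for AREG withdrawal, 20 with ligand present and 23 after withdrawal. Among the lists that fry called, its direction was opposite to that of camera for NRF2 targets on EGF withdrawal (median −0.30), luminal markers on AREG withdrawal (median 0.06) and hypoxia response after withdrawal (median −0.08), lists that camera did not call and whose mean and median differ in sign. An estimated correlation left 9 of the 17 lists called for the difference. Lists called with ligand present numbered between 3 and 5 with 1 array left out, and 5 without AREG present replicate 1. EGFR on EGF withdrawal turned to 0.17 with the mean of its probes, because its second probe rose. Where no reason is given, the cause was not tested. Signal over background limits dim genes: of 563 results of named genes 426 had a probe above background on all 12 arrays, and 424 of these kept direction and side of the threshold.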

Other observations

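The tests of BMP and SMAD targets and of YAP and TEAD targets were set before their results were seen, and the gene groups of the first paragraph were chosen after their values were seen.

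Metallothioneins, which bind zinc and copper, were lower in 6 of 6 measured genes on either withdrawal, with a median of −1.14 for EGF (adjusted p = 0.000155) and −1.63 for AREG (adjusted p = 3.32e-06). MT1G had the largest fall, at −3.00 (SE 0.09) and −4.95 (SE 0.09), and MT2A was at −1.75 (SE 0.08) and −2.05 (SE 0.08). Kallikreins, secreted serine proteases, were higher in 4 of 6 genes on EGF withdrawal (median 1.23, adjusted p = 0.00719; adjusted p = 0.0512 with an estimated correlation) and in 6 of 6 on AREG withdrawal (median 1.61, adjusted p = 7.23e-06). With ligand present they were lower in AREG than in EGF in 5 of 6 and higher in 1 (median −2.13, adjusted p = 6.62e-06). Replication-dependent histone genes were higher in 11 of 15 and lower in 1 on EGF withdrawal (median 0.69, adjusted p = 0.000434), and higher in 8 of 15 and lower in 2 on AREG withdrawal (median 0.30, adjusted p = 0.0309; adjusted p = 0.0541 with an estimated correlation). The calls of kallikreins on EGF withdrawal and of histones on AREG withdrawal were thus lost. H2BC5 rose by 2.50 (SE 0.09) and 1.36 (SE 0.09) while H4C3 was at −2.67 (SE 0.08) and −3.78 (SE 0.08). Probes of these families can detect more than 1 member. Which forms of the histone transcripts the probes detect was not tested, so the rise in histone signal does not speak for histone synthesis in S phase.

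ID1 is a direct target of BMP signalling, and it rose on EGF withdrawal and fell on AREG withdrawal. A hypothesis is that BMP and SMAD signalling may differ between the withdrawals, so that its other targets move with ID1. In the difference of the responses, 7 of 11 other targets were lower and 1 higher (median −0.51, camera p = 0.00223, or 0.0155 with an estimated correlation), which was the direction predicted. Against it, the list was called neither on EGF withdrawal (median 0.35, adjusted p = 0.131) nor on AREG withdrawal (median 0.02, adjusted p = 0.694), so that the targets as a set did not move as ID1 did. ID3, a close relative of ID1, rose on both, by 2.11 (SE 0.08) and 0.73 (SE 0.08). BAMBI, a decoy receptor, had a difference of −1.51 (SE 0.17) and ID3 one of −1.38 (SE 0.12). Ligands and receptors of the pathway were not tested, and other regulators of these genes stay open.

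CCN2, a target of YAP and TEAD, differed in its response to the 2 withdrawals, by −3.78 (SE 0.14). If YAP activity differed, which may follow from a difference in cell density or shape, its other targets would move with CCN2. In the difference of the responses, 9 of 15 were lower and 3 higher (median −0.41). The list was lower by camera of limma, with an adjusted p = 0.0325 over the 5 lists tested here. With an estimated correlation the adjusted p was 0.0647, so that the evidence is weak. The list was lower on AREG withdrawal (median −0.33, adjusted p = 0.0309, or 0.0541 with an estimated correlation) and was not called on EGF withdrawal (median −0.13, adjusted p = 0.409). With ligand present, 9 of 15 genes were higher in AREG than in EGF and 2 lower (median 0.35, adjusted p = 0.00998, or 0.0381 with an estimated correlation). After withdrawal the list was not called between the ligands (median −0.02, adjusted p = 0.531). Its call in the difference thus goes with a higher level before AREG withdrawal rather than a lower one after it. CCN2 itself had means of 9.81 with EGF present, 9.72 after EGF withdrawal, 11.37 with AREG present and 7.49 after AREG withdrawal. CCN2 was thus also lower after AREG than after EGF withdrawal, which the other targets as a set were not.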
